A study of Mus musculus with 45 samples.

How the data were processed

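Expression was measured on Affymetrix mouse 3' arrays in 45 samples: WT, SCR and KD-labelled murine ESCs and their EBs of 4, 8, 12 and 16 days, with 3 arrays for each of 15 groups. The values used were the deposited log2 signals of 45037 probe sets, which the authors had processed and rounded to 2 decimals. Per the submitters' processing notes, Affymetrix Expression Console, Partek 6.6 and RMA were used; the notes give no role or order for them, so which of them made the values is not known, and the raw scans were not used here. Values ran from 1.82 to 14.26, and array medians from 5.02 to 5.18. The share of identical values between 2 arrays of the same group was at most 2.22%. Replicate arrays correlated at 0.9888 to 0.9961 over probe sets.

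Samples were grouped by their titles, line and day. The first 8-day array of each line carries the tag of undifferentiated ESCs in another label field, and it was kept with the 8-day EBs named in its title. The SCR titles number the arrays 4 to 6, so the replicate numbers were taken from the source names. The design, the lists of genes, the rule for named genes and all alternatives but 1 were chosen before the data were examined.

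Probe sets were joined to genes by the annotation supplied for the platform. Of the probe sets, 34945 carried 1 gene symbol, 932 several and 9160 no listed gene; the last 2 kinds entered no test of genes. The 204 probe sets whose gene is missing from the reference table kept their symbol. Where several probe sets named the same gene, the one with the highest mean over all arrays stood for it, which gave 18193 genes; no filter on level was applied. The RefSeq gene table of assembly GRCm38.p6 served only for names and chromosomes, and no sequence was aligned. Among 2203 pairs of a named gene and a comparison, 1155 had more than 1 probe set, and in 19 a further probe set was called in the opposite direction.

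A linear model with a mean for each line and stage was fitted to all 45 arrays (limma 3.58.1, R 4.3.3, with version 1.17.8 of the package data.table), so that all groups shared an estimate of the spread, with 30 residual degrees of freedom and 5.17 from the empirical Bayes prior. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes within each comparison, and calls of at least 2-fold were counted beside them. The comparisons were KD-labelled against SCR, KD-labelled against WT and SCR against WT at each of 5 stages, each EB day against ESCs within each line, and a moderated F test of whether KD minus SCR changed with stage. Standard errors are those of limma, and SDs are those of 3 arrays. Genes set apart from both controls were those called in the same direction against SCR and WT. Beside them stand the number from independent lists and that from 20 simulations, with KD-labelled arrays drawn around the midpoint of the SCR and WT means.

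For 21 lists of genes the members called up and down were counted over all genes and adjusted over the list alone, and each list was tested by limma's camera with a preset correlation of 0.01 and again with an estimated correlation, and by fry, which asks whether genes move on balance in a single direction. The p-values of camera were adjusted over lists and stages, 105 tests for each comparison of lines and 84 for each line over time. The lists covered pluripotency, primed epiblast, primitive streak and early mesoderm, endoderm, cardiac muscle, mesenchyme and smooth muscle, endothelium, blood, neural, trophoblast, germline and 2-cell-like cells, Hox genes, the STRIPAK complex, TRIM28 and heterochromatin silencing, cell cycle, interferon response, p53 targets, hypoxia and glycolysis, Wnt and TGF-beta family targets, imprinted and Y-linked genes. The primed epiblast list and the list of Wnt and TGF-beta family targets share Lef1.

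Named genes followed a fixed rule, and symbols that are only clone or locus numbers were never named. They are Strip2; at each stage the 5 largest rises and 5 largest falls against SCR among genes called in the same direction against both controls with all 3 KD-labelled arrays beyond all 6 control arrays; the 10 largest mean rises and falls among genes meeting this at all 5 stages; up to 5 mean rises and falls among genes called between SCR and WT at all stages; the 10 largest rises and falls by day 16 in WT; the 10 genes with the widest range of KD minus SCR over stages; and up to 4 called members of each list with the largest change.

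Progress along the WT course was the least-squares slope of each array's deviation from the WT ESC mean on the WT day 16 change, over the 4641 genes called with at least a 2-fold change. KD-labelled and SCR slopes were compared over the EB days by all 160000 permutations of arrays within days. Chromosome medians used the 9083 genes with a mean level above the median and a listed chromosome. The procedure was tested on simulated data: changes planted in 50 genes at each of 4 sizes were recovered in 56% of genes at 1.5-fold, 94% at 2-fold, 98% at 3-fold and 100% at 4-fold, with 9 false calls among 183, and all 174 recovered genes had the right sign.

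Alternatives were the probe set with the largest SD, leaving out dim genes (below the median of mean levels), centring each array on its median, cyclic loess, a trended and robust prior, a fit of only the groups compared, the chip number as a replicate block over all arrays and within lines, and leaving out each replicate in turn; for progress also other gene sets. Leaving out the genes of chromosomes 15, 19, X and Y was added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.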

Results

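The series followed murine embryonic stem cells (ESCs) as they formed embryoid bodies (EBs), the cell aggregates in which stem cells grown by hanging drop give rise to derivatives of the germ layers. It compared 3 lines: untransfected wild-type cells (WT), cells carrying a scrambled control construct (SCR) and cells labelled as silenced for Strip2 (KD). Strip2 encodes a protein of the STRIPAK complexes, assemblies of striatins, kinases and the phosphatase PP2A. Each line was measured as undifferentiated ESCs and as EBs of 4, 8, 12 and 16 days, with 3 arrays for each line and stage, so that 45 arrays in 15 groups held the levels of 18193 named genes. Array medians lay between 5.02 and 5.18 on the log2 scale, and replicate arrays correlated at 0.9888 to 0.9961 across probe sets, which are not independent of each other. The number of arrays in a group limits the precision of every value, and nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

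The targeted gene was examined first, in every array. The single Strip2 probe set stood at 2.7 ± 0.27 in WT ESCs, 2.85 ± 0.02 in SCR ESCs and 2.72 ± 0.06 in KD-labelled ESCs (log2 level, SD, n = 3), among the dimmest probe sets of those arrays. KD minus SCR was -0.13 in ESCs (SE 0.19, limma adjusted p = 0.71), 0.46 at day 4 (adjusted p = 0.052) and 0.04 at day 8 (adjusted p = 0.88). Strip2 rose in SCR EBs late in the course, to 4.67 ± 0.21 at day 12 and 4.85 ± 0.66 at day 16, and there the KD-labelled EBs were lower by log2 differences of -0.92 (adjusted p = 1e-04) and -1.56 (adjusted p = 8.6e-09). Against WT, however, the KD-labelled EBs were higher at day 12, by 0.63 (adjusted p = 0.0061), and at day 16 the difference was 0.4 (adjusted p = 0.07). SCR itself lay above WT by 1.55 at day 12 (adjusted p = 4.1e-07) and by 1.97 at day 16 (adjusted p = 1.3e-09). The probe set thus shows no lower Strip2 level in the line labelled Strip2-silenced than in WT at any stage, and the line is called KD-labelled throughout. Each direction given for it rests on its label.

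**Figure D1:**
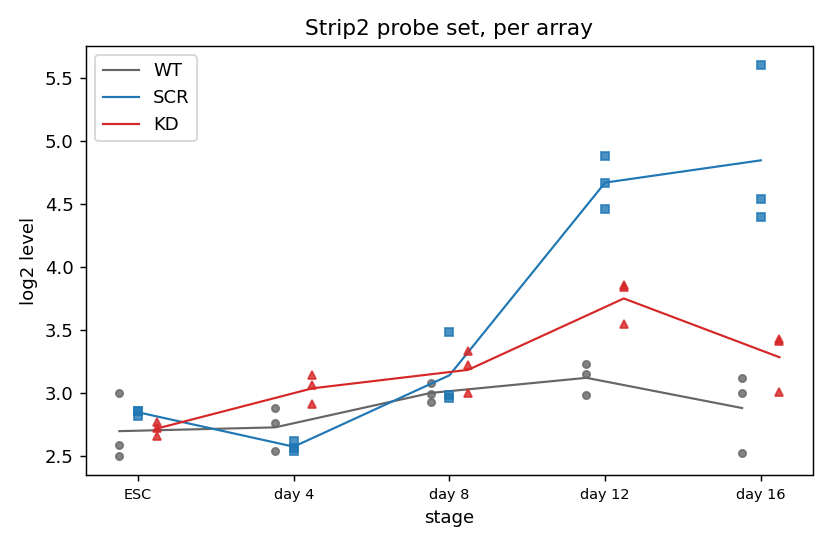
Log2 level of the Strip2 probe set (vertical axis) in each array by stage (horizontal axis); points are arrays, 3 per line and stage, and lines join the group means of WT, SCR and KD-labelled cells. SCR rises to 4.85 at day 16, while the KD-labelled mean lies at 3.28 and the WT mean at 2.88.

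The comparison of KD-labelled with SCR ESCs asks how the lines differed before differentiation. The core pluripotency factors Pou5f1 and Sox2, chosen after their values were seen, differed by -0.12 (SE 0.37, adjusted p = 0.87) and -0.14 (SE 0.34, adjusted p = 0.84). Genes of the primed epiblast, the later pluripotent state, were lower in KD-labelled than in SCR ESCs, with a mean list level of 7.02 ± 0.04 in KD-labelled, 8.77 ± 0.35 in SCR and 7.57 ± 0.62 in WT ESCs (SD, n = 3). Against SCR, 8 of the 11 listed genes fell (9 adjusted over the list alone), with a median of -1.91, among them the POU factor Pou3f1 (-3.07), the growth factor Fgf5 (-3.06), Sall2 (-3.03) and the claudin Cldn6 (-2.42). The list's adjusted p was 1.7e-08 by camera and 0.016 with an estimated correlation. Against WT 3 of the 11 were lower (adjusted p = 0.02, and 0.35 with an estimated correlation). The largest rises set apart from both controls were Bhmt, the betaine-homocysteine methyltransferase, at 7.79 ± 0.27 against 3.79 ± 0.5 (SD, n = 3, 15.9-fold, SE 0.37 log2, adjusted p = 2e-10), the metallothionein Mt4 (15.6-fold), the homeobox genes Crxos (11.8-fold) and Rhox5 (10.7-fold), and Aard (9.43-fold). The largest falls were Gbp2 (-4.33, SE 0.43, adjusted p = 6.3e-10) and Gbp2b (-3.89), both interferon-inducible GTPases, the RNA-binding protein gene Samd4 (-4.27), Fndc3c1 (-4.08) and the smooth muscle actin-binding protein gene Tagln (-3.76). All of these sizes are against SCR. SCR ESCs themselves lay above WT for Tagln and below WT for Aard, as given further below, so these genes differed less from WT.

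Among the other lists in ESCs, 8 of 16 germline genes rose (12 adjusted over the list alone; adjusted p = 0.0091, and 0.061 with an estimated correlation). Foremost was Usp17la (3.1), a marker of 2-cell-like cells. Of 25 endoderm genes 7 rose and none fell (adjusted p = 0.016, and 0.28 with an estimated correlation). These included the transcription factors Gata6 (2.34) and Sox17 (1.7). Of 21 neural genes 7 fell and 1 rose (adjusted p = 0.0039, and 0.4 with an estimated correlation). Gap43, a growth cone protein gene, stood at -2.66. Of 14 p53 targets 5 fell (adjusted p = 0.0052, and 0.19 with an estimated correlation). The fall of Perp was -1.44. The pluripotency list had 5 of 28 genes up and 3 down (adjusted p = 0.37). The T-box gene Tbx3 stood at 2.61 and Dppa3 at -2.14. In all, 4297 of 18193 genes were called, 2233 up and 2064 down, of which 918 changed at least 2-fold. Rises made up 52% of these calls, 59.4% with arrays centred on their medians and 49.7% after cyclic loess.

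At day 4 the KD-labelled EBs retained pluripotency transcripts that SCR EBs had lost, and most genes of the primitive streak and early mesoderm list were lower than in SCR EBs. Zfp42 (Rex1), a marker of naive ESCs, stood at 11.72 ± 0.12 against 4.07 ± 0.71 (SD, n = 3, log2 difference 7.65, SE 0.46, adjusted p = 1.9e-16), and the nuclear receptor gene Nr0b1 at 10.37 ± 0.14 against 2.95 ± 0.05 (7.42). Of the 28 pluripotency genes 24 were higher and 1 lower (26 adjusted over the list alone), with a median of 4.06 (adjusted p = 5.8e-19, and 0.0093 with an estimated correlation). The primitive streak and early mesoderm list had 11 of 16 genes lower and 1 higher, with a median of -2.32 (adjusted p = 8.2e-07, and 0.051 with an estimated correlation): the homeobox genes Mixl1 (-4.55), Evx1 (-3.88) and Lhx1 (-3.78) and the T-box gene Eomes (-3.87), which act at gastrulation. Of the 17 Wnt and TGF-beta family targets 13 were lower and 2 higher, with a median of -2.92 (adjusted p = 2e-08, and 0.01 with an estimated correlation). Among them were Msx2 (-5.54), the BMP-induced inhibitor gene Smad6 (-5.3) and Msx1 (-4.6), while the Nodal antagonist gene Lefty2 was higher (4.44).

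The largest single falls at day 4 were the apelin receptor gene Aplnr (-8.67, SE 0.2, adjusted p = 1.6e-27), the mesenchymal cadherin Cdh11 (-8.18), Rgs5 (-7.96), Asb4 (-7.61) and the co-receptor gene Nrp1 (-6.62). Beside Zfp42 and Nr0b1, the largest rises were the muscle fusion gene Mymx (7.9), Mageb16 (7.51) and the germline gene Morc1 (7.16). Of the cardiac list, the transcription factor genes Hand2 (-5.95), Tbx20 (-5.94) and Isl1 (-3.45) were lower and Myh6 (2.9) was higher. In all, 11 of 29 cardiac genes fell and 3 rose (adjusted p = 0.012, and 0.56 with an estimated correlation). Of 21 mesenchyme genes 10 fell and 2 rose (adjusted p = 0.0035, and 0.2 with an estimated correlation). Foremost were Snai2 (-4.13) and Pdgfrb (-4.01). Endothelial genes went both ways, 6 up and 3 down of 16 (adjusted p = 0.68). The VEGF receptor gene Kdr stood at -4.79. Of 29 Hox genes 9 fell and 2 rose (adjusted p = 0.019, and 0.2 with an estimated correlation), Hoxd1 by -4.58. The call covered 7722 genes, 4109 up and 3613 down, of which 2639 changed at least 2-fold. Rises made up 53.2% of these calls, and 45.4% with arrays centred on their medians. Aplnr, at 2.61 in KD-labelled EBs, lay near the lowest values of the arrays, and Rgs5 (3.09) and Cdh11 (3.15) were also dim there. This limits how exactly their differences and order can be read.

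At day 8 the cardiac, mesenchyme and blood lists were lower in KD-labelled than in SCR EBs. Col3a1, a fibrillar collagen gene, stood at 3.96 ± 0.29 in KD-labelled and 14.08 ± 0.15 in SCR EBs (SD, n = 3, log2 difference -10.13, SE 0.28, adjusted p = 6.2e-26). The embryonic globins Hbb-bh1 (-10.01, SE 0.43) and Hbb-y (-9.78), and the matrix genes Lum (-9.37) and Postn (-8.5), followed. The SCR level of Col3a1 lies near the highest value on the arrays, 14.26, and the KD-labelled level below the array medians, which limits how exactly the difference can be read. Of 29 cardiac genes 26 fell (27 adjusted over the list alone), with a median of -3.39 (adjusted p = 4e-15, and 0.045 with an estimated correlation). Cardiac troponin T (Tnnt2) differed by -8.41, Actc1 by -7.38 and the ventricular light chain Myl2 by -6.84. Mesenchyme genes fell in 19 of 21 cases (median -3.77, adjusted p = 2.2e-13, and 0.003 with an estimated correlation), and blood genes in 12 of 15, with 2 higher (median -2.57, adjusted p = 5e-08, and 0.017 with an estimated correlation). All 28 pluripotency genes were higher, with a median of 4.24 (adjusted p = 4.8e-20, and 0.0072 with an estimated correlation). Foremost were Zfp42 (8.45), Dppa2 (7.77), Nanog (7.72) and Fbxo15 (7.4). Mageb16 was higher by 7.5.

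Endothelial genes were lower at day 8 in 11 of 16 cases and higher in 1 (adjusted p = 2.2e-05, and 0.056 with an estimated correlation). Kdr stood at -4.59 and the sialomucin gene Emcn at -4.3. Some streak genes lay above SCR by this day: 8 of 16 were higher and 1 lower, which did not pass the list test (adjusted p = 0.076). The signalling gene Nodal stood at 4.15 and Eomes at 2.81, while the mesenchymal regulator Foxc1 was lower (-3.85). Primed epiblast genes were higher in 7 of 11 cases and lower in 2 (adjusted p = 0.029, and 0.37 with an estimated correlation). Among them were Otx2 (4.66) and Fgf5 (3.9). Endoderm genes went both ways, 7 up and 10 down of 25 (adjusted p = 0.67). Cubn, the cubilin of absorptive visceral endoderm, stood at 5.8 and Amn, its partner amnionless, at 3.35, against Rbp4 at -3.31 and alpha-fetoprotein (Afp) at -2.62. Neural genes also went both ways, 5 up and 3 down of 21 (adjusted p = 0.87). The day 8 call covered 9597 genes, 5103 up and 4494 down, of which 3661 changed at least 2-fold. Rises made up 53.2% of these calls, 59.3% with arrays centred and 48.5% after cyclic loess.

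At days 12 and 16 the pluripotency list stayed higher and the cardiac and mesenchyme lists lower in KD-labelled EBs than in SCR EBs. Of 28 pluripotency genes 26 were higher on each day, with medians of 4.54 and 4.92 (adjusted p = 2.4e-17 and 8.8e-15, and 0.01 and 0.016 with an estimated correlation). Fgf4 differed by 7.04 and 6.84 and Zfp42 by 7.2 and 6.75 on the respective days. Albumin (Alb), the main plasma protein of liver, reached 13.48 ± 0.52 in SCR EBs at day 16 against 4.02 ± 0.15 in KD-labelled EBs (SD, n = 3, log2 difference -9.46, SE 0.23, adjusted p = 6.1e-28). The protease gene Cym (-9.18), the proteoglycan gene Dcn (-8.51), Tnnt2 (-8.43) and Lum (-8.4) were the next largest falls at day 16, and Lum (-9.07), Dcn (-8.45), Tnnt2 (-8.3), Col3a1 (-8) and Actc1 (-7.88) those at day 12.

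Cardiac genes were lower in 27 of 29 cases on both days, with 1 higher at day 12 and none at day 16, and medians of -4.07 and -4.3 (adjusted p = 4e-15 on each day, and 0.045 on each with an estimated correlation). Mesenchyme genes were lower in 18 and 19 of 21 cases, with 2 and 1 higher and medians of -4.74 and -4.87 (adjusted p = 1.4e-14 and 4e-15, and 0.0021 and 0.0019 with an estimated correlation). Endothelial genes were lower in 12 and 10 of 16 cases and higher in 2 and 3 (adjusted p = 0.00043 and 0.0017, and 0.12 and 0.17 with an estimated correlation). VE-cadherin (Cdh5) stood at -4.07 and -4.66. Blood genes were lower in 12 of 15 cases at day 12, with 2 higher (adjusted p = 0.00049, and 0.13 with an estimated correlation), and went both ways at day 16, 4 up and 3 down (adjusted p = 0.62). Of 25 endoderm genes 8 were higher and 11 lower at day 12 (adjusted p = 0.39), and 7 higher and 16 lower at day 16 (adjusted p = 0.0035, and 0.18 with an estimated correlation), the latter with the fibrinogen genes Fgg (-6.97) and Fgb (-6.39) and the apolipoprotein gene Apoa1 (-5.35). Neural genes were lower in 12 of 21 cases and higher in 4 at day 16 (adjusted p = 0.0025, and 0.39 with an estimated correlation). The radial glia gene Fabp7 stood at -5.82. At day 12, 4 neural genes were higher and 7 lower (adjusted p = 0.3).

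Streak genes were higher in 12 of 16 cases and lower in 1 at day 16 (adjusted p = 0.037, and 0.44 with an estimated correlation). Nodal stood at 4.6. At day 12, 7 streak genes were higher and 1 lower (adjusted p = 0.11). Primed epiblast genes were higher in 8 and lower in 2 of 11 cases at day 12 (adjusted p = 0.037, and 0.39 with an estimated correlation) and higher in 6 and lower in 1 at day 16 (adjusted p = 0.11). The methyltransferase gene Dnmt3b stood at 3.58 and 3.88. Among the largest rises were, at day 16, Mageb16 (7.39), Morc1 (7.26), the synaptonemal complex gene Sycp3 (7.13) and Mymx (7.04), and at day 12 Dppa2 (7.24), Zfp42, Mageb16 (7.07), Fgf4 and Mymx (7.04). Calls numbered 10115 at day 12, 5633 up and 4482 down, with 3910 at least 2-fold, and 12117 at day 16, 7233 up and 4884 down, with 4262 at least 2-fold. The share of rises was 55.7% at day 12 and 59.7% at day 16. It was 63.8% and 71.7% with each array centred on its median and 49.1% and 48.4% after cyclic loess, so the balance of rises and falls depends on the scaling. Leaving out dim genes gave 6508 and 6675 calls at days 12 and 16.

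**Figure D2:**
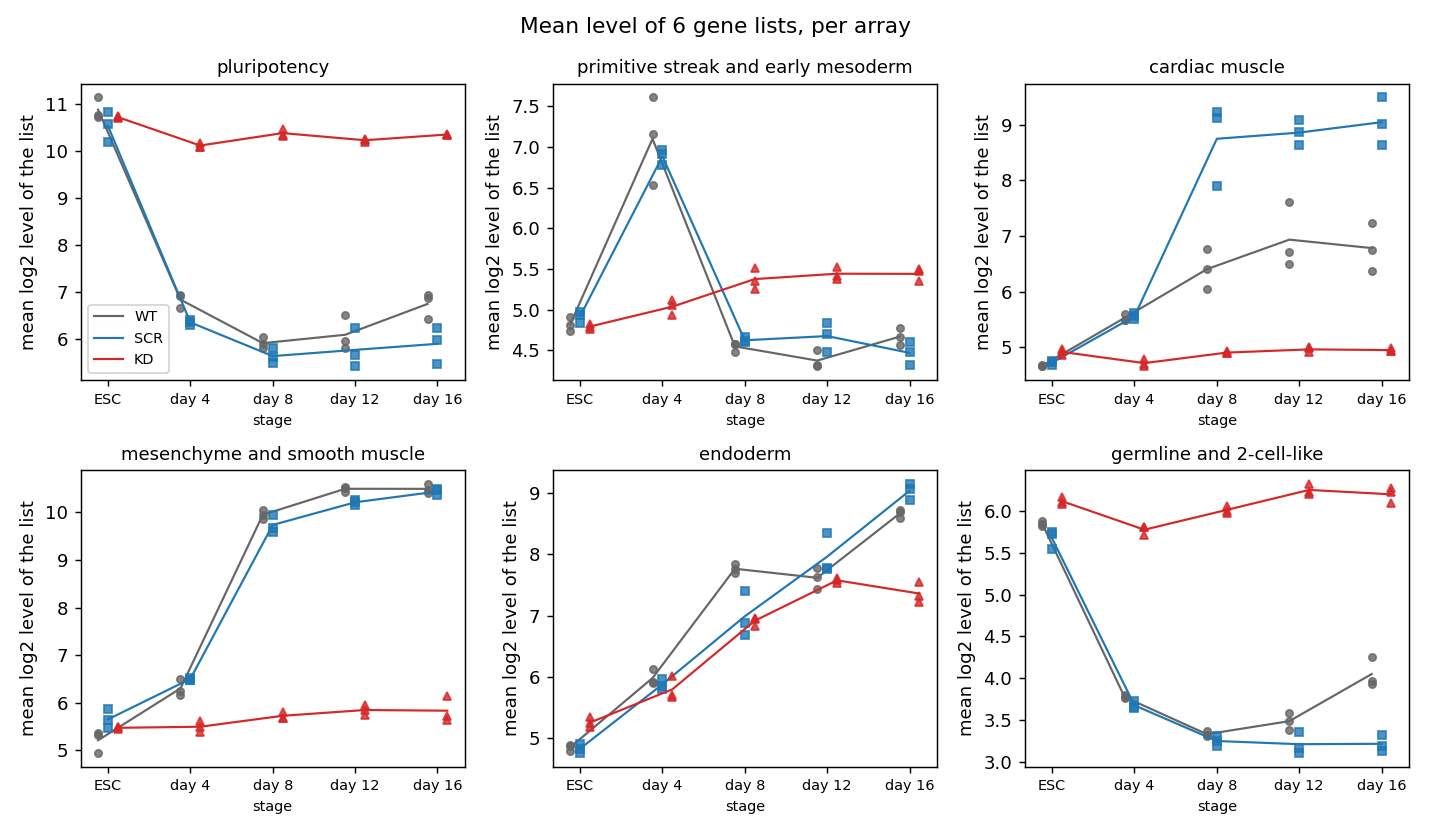
Mean log2 level of the genes of 6 lists (vertical axis) in each array by stage (horizontal axis); points are arrays, 3 per line and stage, and lines join group means. The pluripotency mean falls from 10.53 to 5.89 in SCR between ESCs and day 16, and stays between 10.11 and 10.72 in KD-labelled cells.

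Lists chosen for the labelled target and for chromatin differed between KD-labelled and SCR cells at most stages. SCR cells had themselves moved. From ESCs to day 16 the mean TRIM28 level went from 9.47 to 8.25 in SCR and from 9.62 to 9.34 in KD-labelled cells. Germline means went from 5.67 to 3.21 and from 6.12 to 6.2, and imprinted means from 7.63 to 8.85 and from 7.29 to 7.57. STRIPAK means rose in both, from 9.1 to 9.35 and from 8.76 to 8.95. Whether the differences go beyond this was not tested. Of 18 STRIPAK genes, 8 fell in ESCs, 10 at each of days 4, 8 and 12, and 9 at day 16, and none rose (adjusted p = 0.00015 to 0.0051, and 0.003 to 0.017 with an estimated correlation). The kinase genes Stk24 (-1.14 in ESCs) and Stk26 (-1.74 in ESCs) led the list at first, and medians lay between -0.37 and -0.23. The list of TRIM28 and heterochromatin silencing genes had 5 up and 2 down of 20 in ESCs (adjusted p = 0.11) and 14, 16, 15 and 19 up with none down in EBs (adjusted p = 0.0011, 1.1e-05, 0.00019 and 9.6e-06, and 0.045, 0.01, 0.02 and 0.01 with an estimated correlation). Zfp819 led it at each EB stage (3.3 to 4.08), ahead of Zfp57, the zinc finger gene that protects imprints (1.19 to 1.79). Germline genes were higher in 11, 13, 14 and 15 of 16 cases over the EB days, with 1 lower at day 4 only and medians of 1.45, 2.05, 2.72 and 2.27 (adjusted p = 2.9e-07, 1.9e-08, 4.1e-09 and 7.5e-08, and 0.0016, 0.00094, 0.00094 and 0.0012 with an estimated correlation). Dnmt3l, the cofactor of de novo methylation, was higher than in SCR EBs by 6.23 to 6.53, and the difference of the piRNA pathway gene Mael reached 6.26.

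Hox genes were lower in 20, 17 and 15 of 29 cases at days 8, 12 and 16, and higher in 1, 2 and 3 (adjusted p = 1.5e-06, 3.4e-05 and 0.0039, and 0.01, 0.02 and 0.12 with an estimated correlation), with Hoxb2 between -3.32 and -3.06 on those days, and had 2 up in ESCs (adjusted p = 0.67). Imprinted genes were lower in 13, 14, 16 and 13 of 20 cases over the EB days and higher in 5, 3, 3 and 3 (adjusted p = 3.4e-05, 4.5e-06, 8.2e-06 and 0.00029, and 0.021, 0.016, 0.016 and 0.045 with an estimated correlation). The Notch-like gene Dlk1 stood at -6.75 at day 8 and Peg3 at -3.87 at day 4. In ESCs 7 imprinted genes fell and 3 rose (adjusted p = 0.012, and 0.17 with an estimated correlation), with a median of -0.01 that turned to 0.03 when arrays were centred. Cell cycle genes were higher in 13, 16 and 19 of 21 cases at days 8, 12 and 16, with 1 lower each time (adjusted p = 0.0057, 0.0015 and 1e-05, and 0.39, 0.32 and 0.16 with an estimated correlation). Foremost was the checkpoint kinase gene Bub1 (1.05, 1.2 and 1.93). Of 3 Y-linked genes, Uty and Eif2s3y were lower at every stage, at -1.47 and -1.09 in ESCs and -3.08 and -1.94 at day 16, and Kdm5d differed by 0.08 in ESCs and 0.37 at day 16 (adjusted p = 0.73 and 0.0086; the list's adjusted p was 0.026 in ESCs, 0.12 with an estimated correlation, and 0.063 to 0.16 in EBs).

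The remaining lists passed at few stages or at none. Targets of p53 were higher in 9 of 14 cases and lower in 1 at day 4 (adjusted p = 0.029, and 0.32 with an estimated correlation), and the apoptosis gene Pmaip1 reached 3.95 at day 12. The mean of the p53 list at day 12 was 9.08 in KD-labelled, 9.14 in WT and 8.46 in SCR EBs, so it was not above WT. Interferon response genes were higher in 10 of 17 cases and lower in 1 at day 12 (adjusted p = 0.025, and 0.39 with an estimated correlation). The tetherin gene Bst2 stood at 3.46. The mean of this list at day 12 was 6.3 in KD-labelled, 6.53 in WT and 5.47 in SCR EBs, so it was not above WT. Hypoxia and glycolysis genes were higher in 14 of 19 cases and lower in 2 at day 12 (adjusted p = 0.02, and 0.49 with an estimated correlation). The glucose transporter gene Slc2a3 stood at 2.16. Trophoblast genes were higher in 2, 6, 6, 9 and 8 of 13 cases and lower in 0, 3, 3, 2 and 3 over the 5 stages, which passed at none (adjusted p = 0.059 to 0.58). Rhox6 stood at 5.5 and the transcription factor Tfap2c at 4.59 at day 8. Over all lists and stages, 58 of 105 tests passed with the preset correlation and 32 held with an estimated one. Median, mean and test differed in sign for endoderm and trophoblast at day 4, blood and p53 targets at day 16, interferon response at day 8, and Wnt and TGF-beta family targets in ESCs and at day 12.

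The comparison of KD-labelled cells with WT asks which differences also hold against untransfected cells. The pluripotency list was higher in 23, 28, 27 and 27 of 28 cases at days 4, 8, 12 and 16, with medians of 3.3, 4.05, 4.19 and 3.69 (adjusted p = 9.7e-20, 3.4e-20, 8e-19 and 1.4e-14, and 0.0057, 0.0057, 0.0063 and 0.017 with an estimated correlation). Mesenchyme genes were lower in 18, 18 and 20 of 21 cases at days 8, 12 and 16 (adjusted p = 3.9e-14, 3.3e-16 and 6.5e-17, and 0.0025, 0.0012 and 0.001 with an estimated correlation). Cardiac genes were lower in 18, 22 and 20 of 29 cases and higher in 2, 1 and 1 (adjusted p = 0.00017, 9.3e-07 and 6.9e-06, and 0.39, 0.26 and 0.31 with an estimated correlation), with medians of -1.2, -1.53 and -1.63, less far from 0 than the -3.39, -4.07 and -4.3 against SCR. The trophoblast list, at 2 up and 8 down of 13, was lower than in WT at day 16 (median -1.62, adjusted p = 0.0046, and 0.13 with an estimated correlation), where the median against SCR was 0.57. The imprinted list passed in ESCs as lower (2 up and 7 down of 20, adjusted p = 0.032, and 0.28 with an estimated correlation) although its median was 0.06. Calls against WT numbered 3355 in ESCs, then 7113, 9084, 9217 and 11053, of which 487, 2321, 3440, 3521 and 3705 changed at least 2-fold, and 58 of 105 list tests passed, of which 25 held with an estimated correlation. With only the compared groups in the fit, the ESC count against WT was 1781. Rises made up 47% of the calls in ESCs and 57% at day 16, and 60.4% and 72.6% with arrays centred on their medians (47.5% at day 16 after cyclic loess).

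Genes that set the KD-labelled line apart from both controls in the same direction numbered 2205 in ESCs, 6244 at day 4, 8014 at day 8, 7987 at day 12 and 9983 at day 16. Dnmt3l, Crxos, Srgn, the testis-expressed ribosomal gene Rpl39l, the auxilin gene Dnajc6, Fmr1nb, the carbonyl reductase gene Cbr3, Rhox5, Mt4 and the autophagy receptor gene Calcoco2 had the largest mean rises among the 341 genes above both controls at all 5 stages. Crxos was higher than SCR by 3.56 (SE 0.2) in ESCs and 6.56 (SE 0.2) at day 16, and Calcoco2 by 3.18 and 3.81. The 333 genes below both at all stages were led by the glypican gene Gpc6, the matrix proteoglycan gene Vcan, the homeobox gene Pbx3, Gas1, Cpe, Adgra2, the imprinted gene Ndn, Tenm3, Cdk14 and Man1a. Vcan lay at -1.78 against SCR in ESCs (SE 0.13, adjusted p = 1.2e-12) and -4 at day 16, and Pbx3 at -3.32 and -3.22. With only the compared groups in the fit the ESC count was 1207, and without dim genes the day 16 count was 5952. Other groupings of the same arrays gave up to 2531 in ESCs, 6530 at day 4, 1003 at day 8, 986 at day 12 and 1595 at day 16. All labels of a stage were shuffled, so some groupings may have kept the KD-labelled arrays together and mixed only the controls. Such groupings would carry the full KD-labelled difference. Opposite calls against the 2 controls were given by 9, 2, 14, 22 and 43 genes at the successive stages. Both comparisons share the KD-labelled arrays. Independent lists would share 395, 1508, 2402, 2582 and 3781 genes, and part of the excess may come from the shared arrays. Simulated KD-labelled arrays placed midway between the SCR and WT means gave 0 genes in each of 20 draws. A level midway between the controls leaves little room for calls in the same direction, so this 0 is no measure of chance. Rises made up 48.2% in ESCs and 57.9% at day 16, and 59.6% and 73.4% with arrays centred on their medians (47.6% at day 16 after cyclic loess).

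The comparison of SCR with WT shows how far the control line departed from untransfected cells. Heart muscle genes were higher in SCR EBs: 24, 25 and 24 of 29 at days 8, 12 and 16 rose and 0, 2 and 1 fell, with medians of 2.24, 2.23 and 2.63 (adjusted p = 5.4e-50, 9.4e-27 and 6.6e-44, and 0.00089, 0.015 and 0.0018 with an estimated correlation). The ventricular light chain gene Myl2 differed by 5.31 (SE 0.49) and the myosin heavy chain gene Myh6 by 5.21 (SE 0.56) at day 8, and the cardiac troponin I gene Tnni3 by 4.42, 3.9 and 4.16 on the 3 days. Trophoblast genes were lower at day 16 in 10 of 13 cases, with a median of -1.27 (adjusted p = 3.7e-27, and 2.3e-06 with an estimated correlation). Foremost were the placental genes Ctsj (-6.24) and Tpbpa (-5.82) and the reproductive homeobox gene Rhox6 (-5.7). Interferon response genes were lower in 10, 14 and 12 of 17 cases at days 8, 12 and 16 (adjusted p = 4.5e-08, 8.2e-15 and 8.1e-23, and 0.047, 0.007 and 0.00087 with an estimated correlation). The deubiquitinase gene Usp18 stood at -2.98 and Oas1a at -2.83 on the last day.

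Endothelial genes were higher in SCR in 9 of 16 cases at each of days 12 and 16 (adjusted p = 2.3e-08 and 1.1e-10, and 0.021 and 0.01 with an estimated correlation). Cdh5 stood at 1.95 and Sox18 at 1.57 on the respective days. Germline genes were lower in 9 of 16 cases at day 16 (10 adjusted over the list alone; adjusted p = 6.5e-11, and 9.8e-05 with an estimated correlation), with Tex19.1 at -2.36. Of 14 p53 targets 4, 10 and 3 fell at days 8, 12 and 16 (adjusted p = 4.7e-06, 1.9e-09 and 0.00061, and 0.045, 0.01 and 0.14 with an estimated correlation), Pmaip1 by -2.01 at day 12. Hypoxia and glycolysis genes rose in 10 of 19 cases at days 12 and 16 (adjusted p = 4.4e-07 and 4.2e-12, and 0.16 and 0.045 with an estimated correlation). Ankrd37 stood at 1.53 and 1.68. In ESCs 7 of 11 primed epiblast genes were higher in SCR (adjusted p = 1.9e-09, and 0.017 with an estimated correlation), Fgf5 by 2.2 and Sall2 by 1.87. The mean level of that list varied between single ESC arrays, at 7.575, 8.194 and 6.955 in WT and 9.075, 8.834 and 8.388 in SCR. A grouping of SCR arrays 1 and 2 with WT array 2 against the rest called 1940 genes in ESCs, more than the 1847 between the lines. Also in ESCs, 5 of 28 pluripotency genes were lower (adjusted p = 0.0094, and 0.51 with an estimated correlation), Tbx3 by -1.54. At day 16, 13 of 28 pluripotency genes were lower (20 adjusted over the list alone; adjusted p = 5.7e-08, and 0.14 with an estimated correlation). Of 25 endoderm genes 10 fell at day 8 (adjusted p = 5.1e-08, and 0.019 with an estimated correlation). Transthyretin (Ttr) stood at -2.22. At day 16, 5 endoderm genes rose and 1 fell (adjusted p = 0.0038, and 0.24 with an estimated correlation).

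Further lists passed between the control lines at some stages, of which those with the smallest p are given. STRIPAK genes rose in 5 of 18 cases in ESCs (adjusted p = 0.0014, and 0.011 with an estimated correlation). Mesenchyme genes rose in 5 of 21 cases in ESCs (adjusted p = 0.0014, and 0.22 with an estimated correlation). Tagln stood at 2.39. Imprinted genes fell in 5 of 20 cases at day 16 (adjusted p = 0.00031, and 0.066 with an estimated correlation). The zinc finger gene Plagl1 stood at -3.45. Cell cycle genes rose in 6 of 21 cases at day 12 (adjusted p = 0.00025, and 0.3 with an estimated correlation), TRIM28 and heterochromatin genes in 4 of 20 (adjusted p = 0.0038, and 0.096 with an estimated correlation), and Wnt and TGF-beta family targets in 7 of 17 (adjusted p = 0.012, and 0.28 with an estimated correlation). Neural genes rose in 5 of 21 cases in ESCs (adjusted p = 0.029, and 0.61 with an estimated correlation), and 2 of 15 blood genes fell at day 8 (adjusted p = 0.018, and 0.37 with an estimated correlation), a list whose median was -0.4, and 0.07 without dim genes. The Hox, streak and Y-linked lists passed at no stage. At day 16 they had 2 up and 5 down of 29 (adjusted p = 0.67), 0 up and 1 down of 16 (adjusted p = 0.22), and none of 3 (adjusted p = 0.57). Without dim genes, however, the Hox list passed at day 16, with a median of 0.4 (camera adjusted p = 0.0262). In all 42 of 105 tests passed, of which 17 held with an estimated correlation, and median, mean and test differed in sign in 18 tests, none of them among the passed.

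Genes called between SCR and WT numbered 1847 in ESCs and 352, 1272, 2678 and 1476 at days 4, 8, 12 and 16, of which 329, 51, 341, 587 and 518 changed at least 2-fold. At all 5 stages only the thioredoxin-related gene Tmx4 was higher in SCR, by 0.44 to 0.75, and 21 genes were lower, led by Tfap2c (-0.9 in ESCs and -2.85 at day 16), the connexin gene Gjb5 (-0.7 and -2.89), Aard (-1.75 and -0.99), the interferon-induced gene Ifi35 (-1.2 and -1.09) and the mitochondrial topoisomerase gene Top1mt (-0.77 and -0.82). These counts moved with single arrays, from 695 without the first SCR ESC array to 2431 without the third in ESCs, 147 without the third SCR array at day 4, 642 without the third SCR array at day 8, and 1448 without the first WT array at day 12, and with only the compared groups in the fit they were 66, 80, 560, 1538 and 698. At day 4 rises made up 31.5% of the calls, and 53.3% with arrays centred on their medians.

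Genes of chromosome 15 differed between the lines as a group. Among genes with a mean level above the median, the 359 on chromosome 15 had a median KD minus SCR difference of 0.607 in ESCs (quartiles 0.357 and 0.858, a 1.52-fold ratio), against -0.013 over all such genes, and 90.8% of them were higher. Relative to WT the median was 0.24 for KD-labelled and -0.35 for SCR ESCs, and it lay at 0.5 and -0.26 at day 16. Of 249 such genes called between SCR and WT at day 4, 111 (44.6%) lay on chromosome 15, which holds 3.9% of the genes, and 158 genes were called there over all levels when chromosomes 15, 19, X and Y were left out, an alternative chosen after seeing the data. Chromosome 19 had a median of 0.167 in KD-labelled against SCR ESCs and 0.423 at day 16, and X of -0.173 and -0.02.

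**Figure D3:**
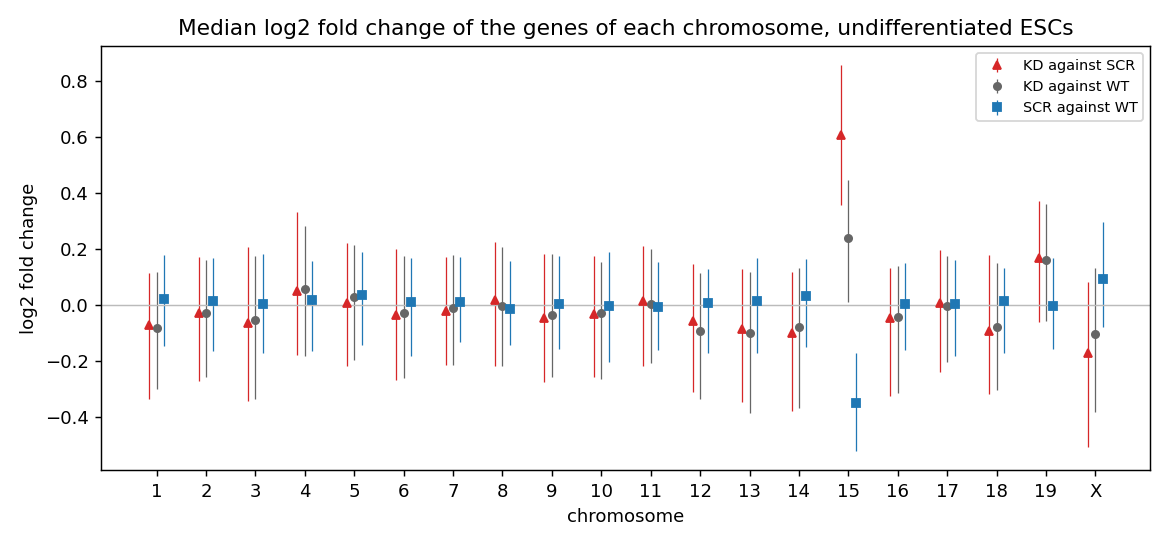
Median log2 fold change of the genes of each chromosome in undifferentiated ESCs (vertical axis) for each chromosome (horizontal axis), over genes with a mean level above the median; points are medians and bars the quartiles of the genes. Chromosome 15 lies at 0.607 for KD-labelled against SCR cells and at -0.35 for SCR against WT.

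The differentiation of WT cells over 16 days gave the course against which the other lines were read. Col3a1 rose from 3.99 ± 0.42 to 14.04 ± 0.04 (SD, n = 3, log2 change 10.04, SE 0.28, adjusted p = 4.9e-26), and transthyretin (Ttr, 9.72), Lum (9.22), the lysozyme gene Lyz1 (8.87), Cdh11 (8.78), Cym (8.73), Dcn (8.69), Alb (8.68), Col1a2 (8.28) and Postn (8.07) followed. The largest falls were Nr0b1 (-7.16), the growth factor gene Fgf4 (-6.52), Dnmt3l (-6.21), the Nodal co-receptor gene Tdgf1 (-6.15), Mymx (-6), the Ras gene of ESCs Eras (-5.8), Zfp936 (-5.72), the nuclear receptor gene Esrrb (-5.7), Morc1 (-5.56) and the oocyte gene Ooep (-5.53). All 28 pluripotency genes fell (median -4.47, adjusted p = 6.1e-15, and 0.014 with an estimated correlation), 20 of 21 mesenchyme genes rose (median 5.71, adjusted p = 3.9e-16, and 0.0025 with an estimated correlation) and 22 of 25 endoderm genes rose and 2 fell (adjusted p = 9.5e-11, and 0.0045 with an estimated correlation). Cardiac genes rose in 21 of 29 cases and fell in 1 (adjusted p = 4.4e-06, and 0.25 with an estimated correlation), trophoblast genes rose in 8 and fell in 2 of 13 (adjusted p = 0.0027, and 0.088 with an estimated correlation), and 20 of 21 cell cycle genes fell (adjusted p = 9.5e-09, and 0.051 with an estimated correlation).

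In SCR EBs the day 16 changes of those 20 genes had the same signs, with Col3a1 at 9.92, Ttr at 10.39, Fgf4 at -6.54 and Nr0b1 at -6.98. In SCR 27 of 28 pluripotency genes fell (adjusted p = 2.6e-14, and 0.019 with an estimated correlation), and 28 of 29 cardiac genes (median 4.19, adjusted p = 1.4e-14, and 0.046 with an estimated correlation), 18 of 21 mesenchyme genes (adjusted p = 6.8e-14, and 0.0042 with an estimated correlation) and 21 of 25 endoderm genes rose, with 3 endoderm genes down (adjusted p = 1.5e-11, and 0.0042 with an estimated correlation). In KD-labelled EBs no change was called for Fgf4 (0.1, SE 0.2, adjusted p = 0.75), Lum (-0.19, adjusted p = 0.46) or Alb (0.06, adjusted p = 0.88). Dnmt3l (-1.31, adjusted p = 7.8e-07), Nr0b1 (-0.97, adjusted p = 0.00049), Esrrb (-0.9, adjusted p = 0.004) and Zfp936 (-0.8, adjusted p = 0.003) fell, while Ttr rose by 8.27 (SE 0.39, adjusted p = 8.9e-18), Col3a1 by 2.81 and Cdh11 by 2.53. Endoderm was the list whose rise by day 16 held with an estimated correlation: 20 of 25 genes were up and none down, with a median of 1.65 (adjusted p = 2.8e-12, and 0.0062 with an estimated correlation). The risen genes included Cubn (4.6), Sox17 (4.1) and Foxa2 (3.94). Of 28 pluripotency genes 9 fell and 2 rose (median -0.35, adjusted p = 0.1), of 29 cardiac genes 5 rose and 2 fell (adjusted p = 0.66), of 21 mesenchyme genes 8 rose and 2 fell (adjusted p = 0.21; the median was 0.05, and -0.15 with arrays centred), and of 11 primed epiblast genes 5 rose (adjusted p = 0.0062, and 0.52 with an estimated correlation), Fgf5 by 4.13. Of 19 hypoxia and glycolysis genes 9 rose and 1 fell (adjusted p = 0.0075, and 0.64 with an estimated correlation), and of 21 cell cycle genes 3 rose and 15 fell (adjusted p = 0.0011, and 0.52 with an estimated correlation).

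Between ESCs and day 16, 12052 genes were called in WT (5114 up, 6938 down), 13065 in SCR (5291 up, 7774 down) and 6939 in KD-labelled cells (3467 up, 3472 down), of which 4641, 4816 and 1543 changed at least 2-fold. The counts at days 4, 8 and 12 were 7581, 10297 and 10911 in WT, 7736, 10597 and 12116 in SCR, and 4343, 6713 and 7899 in KD-labelled cells. Of the 84 list tests of each line over the EB days, 47, 46 and 19 passed and 28, 30 and 3 held with an estimated correlation. Scaling shifted the median of all genes here, by -0.34 in WT, -0.353 in SCR and -0.197 in KD-labelled cells with arrays centred, and by 0.14 and 0.164 in WT and SCR after cyclic loess. The share of rises was 42.4%, 40.5% and 50% as deposited, 24.5%, 24.9% and 24.8% centred, and 52.9%, 51.7% and 53% after loess. In the day 16 comparisons of KD-labelled EBs with SCR and WT the shifts were 0.193 and 0.2 with arrays centred and -0.152 and -0.123 after loess. Without dim genes 6975 and 7089 genes were called in WT and SCR.

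Whether the difference between KD-labelled and SCR cells itself changed with stage was tested by an interaction over the 4 EB days against ESCs. It called 10637 genes, and a fit without dim genes called 6805. The difference of Hbb-bh1 ran from 0.02 (SE 0.43) in ESCs to -10.01 at day 8 and 0.47 at day 16, where SCR EBs had returned to 3.77 ± 0.16 (SD, n = 3). That of Alb ran from -0.05 in ESCs and -0.25 at day 8 to -6.93 at day 12 and -9.46 at day 16, and that of Aplnr was widest at day 4 (-8.67) and -3.34 at day 16. Myh6 was higher in KD-labelled EBs at day 4, by 2.9 (SE 0.56, adjusted p = 4.9e-05), and lower by day 16, at -7.38.

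A single measure placed each array on the course from WT ESCs (0) to WT EBs of day 16 (1), by the slope over the 4641 genes that changed at least 2-fold in WT. WT EBs lay at 0.448, 0.825, 0.941 and 1 at days 4, 8, 12 and 16, and SCR EBs at 0.478 ± 0.004, 0.827 ± 0.021, 0.953 ± 0.02 and 1.022 ± 0.02 (SD, n = 3). KD-labelled EBs lay at 0.094 ± 0.005, 0.191 ± 0.022, 0.253 ± 0.023 and 0.213 ± 0.023 (SD, n = 3). Before differentiation, KD-labelled ESCs lay at -0.003 and SCR ESCs at 0.08 ± 0.044 (SD, n = 3). Averaged over the EB days the difference from SCR was -0.632, against a spread within groups of 0.019, with an exact two-sided permutation p of 1.25e-05, the smallest that the 160000 permutations within days can give. At each single stage the exact permutation p was 0.1, the smallest possible with 3 arrays against 3.

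**Figure D4:**
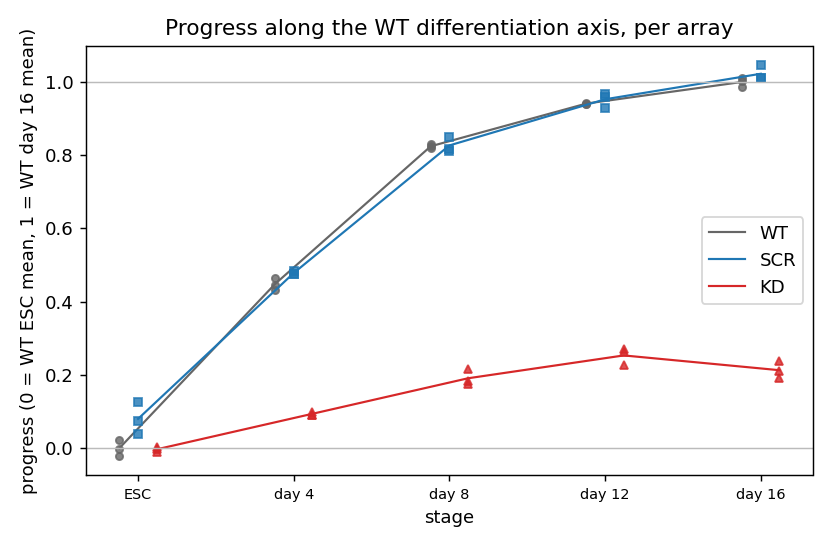
Position of each array along the WT course (vertical axis, 0 for the mean of WT ESCs and 1 for the mean of WT EBs of day 16) by stage (horizontal axis); points are arrays, 3 per line and stage, and lines join group means. WT and SCR EBs run together to 1 and 1.022, and KD-labelled EBs reach 0.253 at day 12 and 0.213 at day 16.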

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

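Among the tests on the 2 patterns weighed in this part, that of gene dosage on 4 chromosomes was fixed before its result was seen, and the others were chosen only after the result was seen. No test for a single outlying array was run, and counts with each replicate left out are given further below.

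The difference between KD-labelled and SCR cells changed with stage for 10637 of 18193 genes by an interaction test, and for 67 of the 69 genes named by the parts of the rule other than the lists, some of which were chosen for such a change, so that this count is no separate evidence. The widest ranges of KD minus SCR over the 5 stages were those of Hbb-bh1 (10.48), Myh6 (10.28), Col3a1 (10.15), Hbb-y (10.01), Lum (9.66), Alb (9.42), Cym (9.22), Myl2 (8.97), Tnnt2 (8.7) and Aplnr (8.61), all in log2 units. Calls were also made in data that no comparison used: of 9160 probe sets with no listed gene, 4040 were called between KD-labelled and SCR EBs at day 16, of which 1004 changed at least 2-fold, against 168 called between SCR and WT. Both are smaller shares than among named genes, of which 66.6% and 8.1% were called in these 2 comparisons.

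The first pattern weighed is that KD-labelled EBs kept pluripotency transcripts and had lower cardiac and mesenchyme lists than SCR EBs from day 8 on. Between KD-labelled day 16 EBs and ESCs 1543 genes were called with at least a 2-fold change, against 1 in the highest other split of those arrays. This argues against RNA of undifferentiated cultures like those on the ESC arrays as the whole cause. The arrays have 10 splits, too few for a share under 0.05, and undifferentiated cultures of another kind or age were not measured. A small share of SCR-like cells among undifferentiated cells was undecided by the range of 6 list medians (permutation p = 0.12). Only listed genes called in SCR with at least a 4-fold rise by day 16 were used. The endoderm list alone, tested only after that value was seen, kept a median of 17.4% of the SCR gain over 20 genes. Over 58 genes of the other lists it was 0.4% (permutation p = 6e-04 after multiplying by the number of lists). This permutation took genes of the same arrays as independent, and the list was picked from the same values, so it cannot exclude an even share. Cubn (1112.2%), Dab2 (417.4%), Sox17 (222.2%) and Foxa2 (133.6%), however, gained more than in SCR. A small share of SCR-like cells cannot give this, which argues against such a share as the whole cause for these genes. The other endoderm genes used gained less than in SCR, from 0% (Alb) to 62.7% (Foxa3). Differences between gains were not tested gene by gene. Chromosomes 15, 19, X and Y held 11.8% of the genes set apart from both controls at day 16 and 10.9% of all tested, so most of those set apart lay elsewhere. With that share of all genes they could not have held most of them, so the test of dosage there could have no other outcome. An effect on other genes through regulators there was not tested. Strip2 silencing and any other difference between the single lines cannot be told apart, because the Strip2 probe set differed by -0.13 between KD-labelled and SCR ESCs and no further silenced line was measured.

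The second pattern is that chromosome 15 genes were higher in KD-labelled and lower in SCR ESCs than in WT. A difference in copy number would move all parts of the chromosome, and the KD minus SCR medians of its 3 parts in gene order were 0.538, 0.673 and 0.572, with 0.538 the lowest, so this explanation may hold but was found from the same values. A few strongly changed genes are excluded, with 90.8% of the 359 genes higher. The median lay at percentile 100 of 10000 random sets matched for level, which argues against the signal level of the genes. That percentile is not particular to chromosome 15, which was picked from the same values. Chromosomes 4 (median 0.05) and 19 also stood at 100, and 14 and X at 0. Single ESC arrays gave chromosome 15 medians relative to WT of -0.36, -0.337 and -0.323 in SCR and 0.24, 0.25 and 0.27 in KD-labelled cells. Whether Strip2 silencing could move the chromosome as a whole was not tested.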

How the results depend on the processing

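The progress difference kept its sign in each alternative run for it (other gene sets, centred arrays, pairing by number and leaving out a replicate), and the signal over background limits the reading of dim genes, Strip2 among them. Strip2 has 1 probe set, so the alternative of another probe set could not test it. Leaving out dim genes, which tests fewer genes, gave 6508 calls at day 12 and 6675 at day 16 for KD-labelled against SCR, 6473 against WT, 572 for SCR against WT and 5952 for both controls at day 16. It gave 6975 for WT and 7089 for SCR from ESCs to day 16, and 6805 for the interaction. A fit of only the groups compared, with fewer samples, gave 1781 for KD-labelled against WT ESCs, 66, 80, 560, 1538 and 698 for SCR against WT at the 5 stages, and 1207 for both controls in ESCs. Without chromosomes 15, 19, X and Y, chosen after seeing the data, SCR against WT at day 4 gave 158 instead of 352. Part of this drop is the removal of called genes. Of the 249 genes above the median level called there, 111 lay on chromosome 15. Other causes of the drop were not tested.

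Leaving out 1 replicate, which leaves fewer samples, gave for SCR against WT 695 (without the first SCR array) to 2431 in ESCs, 147 to 307 at day 4, 642 to 1657 at day 8, 1448 to 3434 at day 12, and 1013 to 1454 at day 16. For KD-labelled against SCR the ranges were 3340 to 4041, 6995 to 7213, 8869 to 9081, 9207 to 9632 and 10924 to 11781 over the stages. Against WT they were 2519 to 3391, 6405 to 6593, 8376 to 8613, 8509 to 8750 and 9742 to 10655. For both controls they were 1755 to 2213, 5657 to 5966, 7402 to 7813, 7287 to 7805 and 8823 to 9711. From ESCs to day 16 they were 10947 to 11631 in WT, 12061 to 12434 in SCR and 5987 to 6468 in KD-labelled cells, and 10143 to 10699 for the interaction. The difference in progress of -0.632 ran from -0.642 to -0.615, and was -0.63 over all called genes, -0.634 over 4-fold genes and -0.643 with arrays centred.

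Reversed values, whose cause was not tested, were as follows. With the probe set of largest SD, KD against WT in ESCs was -0.08 for Dab2 and 0.1 for Top2a, and Ccng1 was 0.26 against SCR in ESCs, 0.56 against WT at day 8 and -0.03 from ESCs to day 8 in KD-labelled cells. Without dim genes, medians were 1.18 for interferon response against SCR at day 8, -0.12 for imprinted genes against WT in ESCs, and 0.07 for blood at day 8 and 0.4 for Hox genes at day 16 in SCR against WT. With arrays centred they were 0.03 for imprinted genes against SCR in ESCs, 0 for interferon response in SCR against WT at day 4 and -0.15 for mesenchyme by day 16 in KD-labelled cells, and after cyclic loess 0.01 for interferon response in SCR against WT at day 4.

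Named genes kept their direction and side of the threshold in 2130 cases and weakened in 36 with the other probe set, 2152 and 18 with arrays centred, 2154 and 17 after loess, and 1310 and 141 with only the groups compared. The first of these checks could change nothing for a gene with 1 probe set, and 1155 of the 2203 pairs had more than 1. Leaving out 1 replicate weakened 524 results of named genes and kept 12500. Of the results of gene lists, 319 kept their call without dim genes, 48 weakened and 7 became stronger. Array numbers were not taken to pair the samples, as not every pair correlated over 0.1: deviations of same-numbered KD-labelled and SCR arrays correlated at -0.21 to 0.39, 7 of 15 over 0.1, and 8 of 15 KD-labelled arrays correlated best with their own number. The mean was 0.032 for arrays of the same number and -0.016 for others, so some sharing by number stays open. The number as a replicate block gave 12176 for KD-labelled against SCR at day 16 and 4372 in ESCs, and it moved no count by over 1.5 times; paired by number, the progress difference was -0.632 (exact sign flips, p = 0.000488).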

Other observations

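The shares of gain given first were computed only after the pattern was seen, and the groupings of arrays were planned before the data were examined. The gain of endoderm transcripts in KD-labelled EBs was uneven, with a median of 17.4% of the SCR gain over 20 genes and values above 100% in Cubn, Dab2, Sox17 and Foxa2 alone, a difference between gains that was not tested gene by gene. As a share of the SCR gain from ESCs to day 16, Cubn, a receptor of absorptive endoderm, stood at 1112.2%, Dab2, its endocytic adaptor, at 417.4%, Sox17 at 222.2% and Foxa2 at 133.6%, while Ttr, a carrier protein of liver and yolk sac, stood at 26.7%, Afp at 4.6%, Apoa1 at 0.9%, Fgb at 0.5% and Alb at 0%. These shares cover only listed genes called in SCR with at least a 4-fold rise by day 16. Their medians were 0.1% for cardiac muscle (23 of 29 measured genes), 0.2% for mesenchyme (17 of 21) and 1% for endothelium (7 of 16). They were 0.6% for neural (4 of 21) and 2.5% for Hox genes (7 of 29).

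Other groupings of the same arrays were counted for each comparison. Each pair of groups of 3 arrays has 10 splits, too few for a share under 0.05, and the labelled split was the largest (1 of 10) except where said. For KD-labelled against SCR the labelled count and the highest other were 4297 and 391 in ESCs, 7722 and 0 at day 4, 9597 and 1 at day 8, 10115 and 0 at day 12, and 12117 and 4 at day 16. For KD-labelled against WT they were 3355 and 454, 7113 and 0, 9084 and 0, 9217 and 1, and 11053 and 1. For SCR against WT at days 4, 8, 12 and 16 they were 352 and 20, 1272 and 67, 2678 and 100, and 1476 and 239. In ESCs the labelled split of SCR and WT gave 1847 and another gave 1940 (2 of 10 as large): it set SCR arrays 1 and 2 with WT array 2 against the rest, so these 6 arrays hold a structure other than the line. From ESCs to day 16 the counts were 12052 and 4 in WT, 13065 and 1 in SCR, and 6939 and 3 in KD-labelled cells.

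For genes set apart from both controls, 100 groupings were drawn, and 3, 4, 1, 1 and 1 of them, the labelled one included, were as large at the 5 stages, with counts of 2205 against a highest other of 2531, 6244 against 6530, 8014 against 1003, 7987 against 986, and 9983 against 1595. For the interaction 1 of 100 was as large, with 10637 against 10173 in the highest other. Its KD-labelled and SCR labels were shuffled separately within each stage. This breaks up the difference between the lines as well as its change with stage, so it does not test the change alone.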
